A study of Drosophila melanogaster with 3 samples.

How the data were processed

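The samples were 3 ChIP-seq libraries from white prepupae that carried a Met transgene tagged with green fluorescent protein. All belonged to 1 group, and the replicate numbers were taken from the labels. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp and the tagged protein was pulled down with an antibody to the tag. Per the text listings deposited with each library, a relaxed peak list was made for each replicate and for the pooled replicates, each against the same control file within a build, and an IDR-thresholded list was derived from these. The aligner, the peak caller and their versions are not given in the sources used here. The labels name the builds dm3 and dm6, and there were 10 deposited lists. The control's reads and signal tracks were not analysed here.

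The deposited lists give a signal value for each peak, as the authors' peak caller wrote it. Its scale depends on the depth of the library, so it was used only to rank and describe peaks within a list. The deposited lists also give the −log10 of each peak's q-value, which reached its highest value in 5752 of the 8513 IDR peaks in dm6 and was not used for ranking. The depth of the libraries is unknown. The IDR set was tested against the pooled list: its 8513 peaks in dm6 are exactly the strongest 8513 of the 30000 pooled peaks, and the lowest signal among them is 98.7. The number of peaks per relaxed list, 30000 in every case, is a ceiling set by the authors and no measure of binding.

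The IDR-thresholded dm6 list was the main set. Each replicate list was taken to its 8513 strongest peaks, so that lists of nearly equal length were compared. Mitochondrial peaks among them were then left out of all but the overlap and the ranks, which left 8513, 8497 and 8506 peaks for replicates 1, 2 and 3. Means and SDs are over these 3 lists. Peaks on the 6 major chromosome arms (2L, 2R, 3L, 3R, X and 4) were used. Sequence came from the RefSeq Release 6 assembly and genes from Ensembl release 115 (BDGP6.54), both in dm6 coordinates; pseudogenes and transposable elements were left out. Coordinates are 1-based. A summit within 500 bp of an annotated TSS counted as near a TSS, and other summits were placed in a 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron or intergenic sequence, in that order of preference.

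Overlap of peaks (at least 1 bp), the share near a TSS and the tRNA genes were tested against 1000 circular shifts of the peaks along each chromosome (100 for the reciprocal and summit rules of overlap). For 15 motifs fixed before the data were examined, presence within 50 bp of the summit on either strand was compared with windows 500 bp to each side, by an exact McNemar test against 1 of the 2 flanks chosen at random. For 22 gene lists the share of genes with a summit within 1 kb of a TSS was compared with 10000 random lists. These were drawn from genes of the same length decile and the same bin of TSS number. Bins above 2 TSSs pooled genes with different numbers of TSSs. Strong and weak peaks were compared by a permutation test of the trend over 5 equal groups by signal, with 100000 resamples. All tests were 2-sided, and adjusted p-values are by Benjamini and Hochberg. The tests of these comparisons, the gene lists and the rule for named genes were chosen before the data were examined. The rule names every gene of the lists for juvenile hormone response and for its receptor and partners, the nearest gene of the 20 strongest IDR peaks, up to 4 genes with the strongest promoter peak of every other list, and every motif. A few members of the lists were left unnamed for length, and 1 that the rule names is not reported here.

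Composition-matched positions, and as many random positions without matching, were added after the data had been seen. From 3000000 random positions outside IDR peaks, 10 were drawn per peak with the same G+C content in bins of 3 bases at the summit (101 bp), 15 bases in the windows 100 to 250 bp away and 12 bases in the windows 450 to 550 bp away. For 12 IDR peaks too few such positions existed, and these peaks were left out of this comparison. Fisher's exact test was used here and treats positions as independent.

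The tests of overlap, TSS share, motifs, gene lists and strong against weak peaks were tested on simulated data with known answers. In 2000 simulated peaks, random positions gave 12.7% near a TSS against 13.4% by chance, and planting 25% at TSSs gave 34.7%. Planting 5% on E-boxes gave 5.80% of peaks with an E-box, and at random positions 0 of the 15 motifs passed against flanks and 1 passed against composition-matched positions. Of 200 random gene lists of 25 genes 4.0% passed p of 0.05, and all lists passed when 12 of their genes were given a peak. Of 200 simulated series without a trend in signal 4.0% passed, and 99.5% passed with a planted trend. Sharing 60% of simulated peaks gave an overlap of 60.3%.

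Alternatives fixed before the data were examined were the stronger 4256 IDR peaks, the replicate lists, leaving out each replicate, reciprocal overlap of 50%, summits within 100 bp, whole relaxed lists, dm3 lists, TSS windows of 250 and 1000 bp, the weakest 10000 pooled peaks as background, motif windows of 100 bp, flanks 1000 bp away, peaks over 1 kb from a TSS, assignment to the gene body with 2 kb upstream, and Fisher's exact test without matching. Without a replicate, only IDR peaks overlapped in both of the others were kept. Analyses used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures Matplotlib 3.10.9.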

Results

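Binding of Methoprene-tolerant (Met) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in white prepupae of *Drosophila melanogaster*, the stage at which the larva has just stopped moving and formed the puparium. Met is a bHLH-PAS protein and a receptor of juvenile hormone. The animals carried a transgene for Met with green fluorescent protein at its C-terminus, and the protein was pulled down with an antibody to the tag from whole animals of both sexes. There was 1 group of 3 biological replicates, each with its own biosample record in the labels, so no condition was compared with another. The comparisons the design allows are between replicates, between peaks and the rest of the genome, and between strong and weak peaks. The deposited dm6 lists held 30000 relaxed peaks for each replicate and 30000 for the pooled replicates. The authors' list thresholded by reproducibility (irreproducible discovery rate, IDR) held 8513. These were the 8513 pooled peaks of highest signal, so membership does not show that a given peak recurred in every replicate. Peak lists hold no read counts, so the depth of the libraries is unknown and no counting interval could be given. Signal values are the authors' own and were used only to rank and describe peaks within a list.

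The peaks with the highest signal in white prepupae lay at Kr-h1, the gene for a zinc finger transcription factor that is induced by juvenile hormone. The 3 strongest of the 8513 IDR peaks all lay in this gene or just upstream of it, and they ranked 1, 2 and 3 in each of the 3 replicate lists as well. The strongest peak (dm6 2L, 6087678 to 6088934, authors' signal 13960.8) lay in an intron of Kr-h1, which spans 6082603 to 6096498 on the plus strand. The summit was at -2912 bp from its nearest TSS, which CG45075 shares with a downstream promoter of Kr-h1. The second peak (6078671 to 6079617, signal 11935.8) had its summit at -3480 bp from the first Kr-h1 TSS, in an exon of the noncoding gene lncRNA:CR9162. The third (6081066 to 6082052, signal 7541.67) had its summit in intergenic sequence at -1145 bp. Kr-h1 also had a weaker peak, of rank 857, with its summit at -140 bp, and 5 peaks in its body and the 2 kb upstream in all. The first and second summits had the palindromic E-box CACGTG within 50 bp (at 6088458 to 6088463 and 6079152 to 6079157). The third had the C-box CACGCG 15 bp away, at 6081470 to 6081475.

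**Figure D1:**
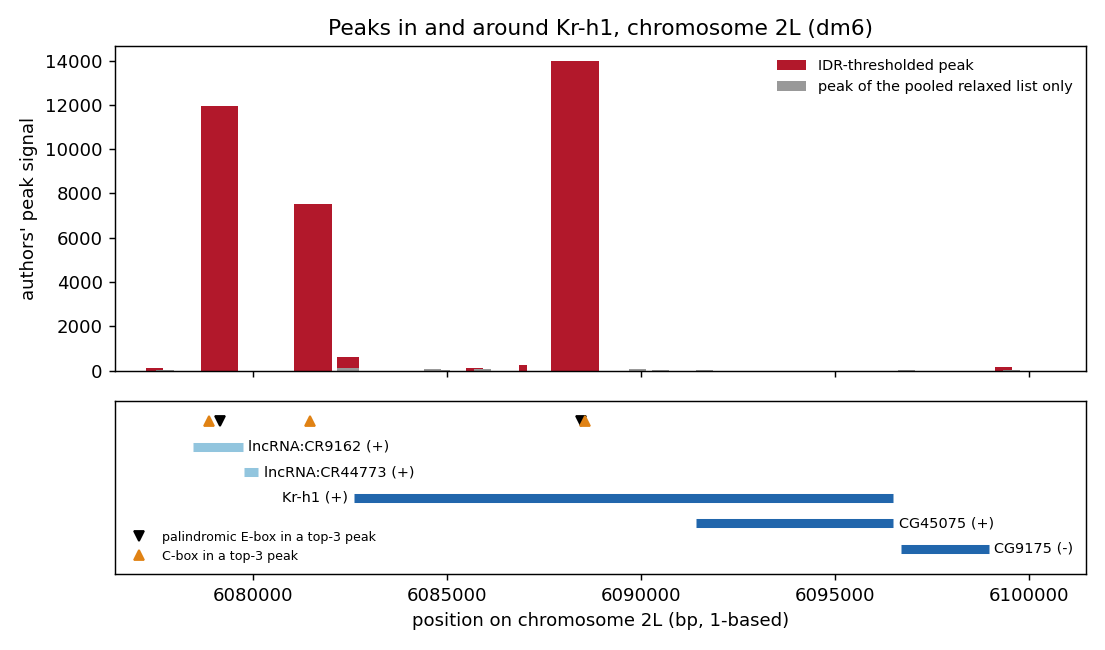
Authors' peak signal (upper panel, bar width is peak width) and annotated genes with strand (lower panel) along chromosome 2L around Kr-h1, in bp of dm6; red bars are IDR-thresholded peaks, grey bars peaks of the pooled relaxed list only, and triangles mark E-boxes and C-boxes inside the 3 strongest peaks. The 3 tall bars reach signals of 13960.8, 11935.8 and 7541.67, and the other peaks in the interval drawn stay at 628.1 or below.

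Below these 3 peaks came a peak between lncRNA:CR46113 and heca on 3R (30270757 to 30271598, signal 4911.88), with a C-box 10 bp from its summit. It ranked 4 in the lists of replicates 2 and 3 and 11 in that of replicate 1. The next were at CG14100 (summit at -88 bp from the TSS), Ugalt (-38 bp), cbt (-1369 bp, in an intron of ush), PNPase (81 bp downstream), CG11050, CG1888, Lk6 and CenG1A. Ranks 13 to 19 were at lncRNA:CR46035 (within osa), Ptp10D, Chro, an intron of Eip75B, CG18549, CG32772 and larp. The summit of rank 20 was intergenic, 11918 bp from its nearest TSS, that of CG13323. The 4 strongest peaks all had an E-box or C-box within 50 bp of the summit, and none of the 96 peaks of rank 5 to 100 did. Elsewhere in those 96 peaks, 8 had an E-box and 14 a C-box. The division after rank 4 was chosen after these values were seen, so no test is given. Met itself (X, 11616124 to 11621280) had no IDR peak within 1 kb of its TSS, in its body or in the 2 kb upstream. The Ptp10D peak of rank 14 (X, 11622863 to 11623371) lay beyond the end of Met with the higher coordinate. The 18 peaks of the pooled relaxed list within 50 kb of Met had a median signal percentile of 82.5 within that list (quartiles 60.4 and 90.8), against 50.1 for the 37 other peaks within 50 kb of Kr-h1. This difference was not tested.

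The peaks were shared between replicates far more than chance allowed. Of the 8513 IDR peaks, 6262 (73.6%) were overlapped by at least 1 bp in the 8513 strongest peaks of all 3 replicates. Circular shifts of the peaks along their chromosomes gave 3.00% on average (permutation test over 1000 shifts, 2-sided, p = 0.0020, the smallest these can give). Single replicates overlapped 87.9% ± 0.490 of the IDR peaks (mean ± SD, n = 3). Exactly 2 replicates overlapped 1480 of the IDR peaks, exactly 1 overlapped 711, and none overlapped 60. The strongest 1703 peaks were found in all 3 replicates in 99.1% of cases, the weakest 1702 in 16.6%. The second value depends on ending each replicate list at 8513 peaks, since with whole relaxed lists 98.3% of all IDR peaks were overlapped in all 3 (7.996% by chance). Across IDR peaks, the ranks of matched summits in pairs of replicates correlated with Spearman's rho of 0.844, 0.840 and 0.842, where peaks are not independent replicates. The IDR set was itself derived from these replicates, and all were called against 1 shared control per build, so the agreement is not independent of either.

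Peaks concentrated at promoters and avoided coding exons. Of the IDR summits, 32.6% lay within 500 bp of an annotated transcription start site (TSS), against 13.4% ± 0.588 (SD) in 1000 circular shifts, a 2.44-fold excess (permutation test, 2-sided, p = 0.0020). The 3 replicate lists, each taken to its 8513 strongest peaks less any mitochondrial ones, gave 35.1% ± 1.33 (SD, n = 3). Introns held 45.0% of summits (39.6% by chance) and intergenic sequence 19.7% (27.4%). Coding exons away from a TSS held 17 summits, 0.200% against 13.7% by chance, and 3′ UTRs 0.728% against 4.45%. At positions matched on G+C the shares were 4.18% and 6.12%. Against circular shifts these 4 shares had a permutation p of 0.0020 (adjusted p = 0.0023 over 7 locations). Against the matched positions, a background added after the data had been seen, the intron call ended and its direction turned (45.1% against 46.2%, Fisher's exact test, adjusted p = 0.0507). The summits near a TSS sat on its upstream side: 76.1% of these 2776 summits were upstream (45.3% by chance, permutation p = 0.0020), at a median position of -121 bp. In the replicate lists the upstream share was 75.4% ± 1.73 (SD, n = 3). The side of the TSS was examined after the data had been seen. The density of IDR peaks was highest on X (71.7 per Mb) and lowest on chromosome 4 (22.99 per Mb, 31 peaks), with 71.4 ± 1.74 and 26.2 ± 4.22 per Mb in the replicate lists (SD, n = 3).

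Against the flanks of the same peaks, the motifs expected for a bHLH-PAS protein were scarcer at the summits. The E-box CACGTG was within 50 bp of 67 of the 8513 summits (0.787%), against 1.33% in windows 500 bp away, a ratio of 0.590 (exact McNemar test, 2-sided, adjusted p = 0.0199 over 15 motifs). The C-box CACGCG was at 121 summits (1.42% against 2.57%, ratio 0.554, exact McNemar test, adjusted p = 2.7e-06). The bHLH-PAS core GCGTG (ratio 0.528), the E-boxes CAGCTG (0.623) and CACCTG (0.594), the GAGA element (0.598) and CA repeats (0.334) were also scarcer, all with adjusted p of 1.2e-05 or less. In the replicate lists the ratio was 0.614 ± 0.0922 for the E-box and 0.552 ± 0.0506 for the C-box (SD, n = 3). With flanks 1000 bp away the calls ended for the E-box (ratio 0.740, adjusted p = 0.152) and the GAGA element (0.765, adjusted p = 0.0848), by the same exact test. Enriched over flanks were 2 core promoter elements, by exact McNemar tests: motif 1, GGTCACACT (31 summits, ratio 3.26, adjusted p = 0.0054), and DRE, TATCGATA (62 summits, ratio 3.18, adjusted p = 4.5e-07). Among peaks over 1 kb from a TSS neither passed (exact tests, ratios of 8.0 and 1.07, adjusted p = 0.0586 and 0.747), and motif 1 did not pass without replicate 3 (adjusted p = 0.0585) or among the 4256 strongest peaks (0.0564). CATATG, Zelda, AP-1, GATA, ecdysone response element and nuclear receptor monomer sites did not pass the test, with adjusted p of 0.119 or more. In all 3 replicate lists, however, Zelda sites were scarcer than in flanks (adjusted p of 0.016 to 0.0483, exact McNemar tests), as were nuclear receptor monomer sites (0.012 to 0.0262). The monomer sites were rare, at 5 summits of the IDR set and at 0.0117%, 0.0471% and 0.0470% of summits in replicates 1, 2 and 3. Among the 4256 strongest peaks CATATG was more frequent (ratio 1.29, exact test, adjusted p = 0.0308) and AP-1 sites scarcer (0.598, adjusted p = 0.0385). GATA sites passed among peaks over 1 kb from a TSS (ratio 1.23, exact test, adjusted p = 0.0064) and in windows of 100 bp to each side (1.22, adjusted p = 0.0057). In those windows CATATG (ratio 1.14, exact test, adjusted p = 0.0306), Zelda (0.667, 0.0057) and nuclear receptor monomer sites (0.308, 0.00079) passed too. AP-1 sites passed without replicate 2 (ratio 0.717, exact test, adjusted p = 0.0159).

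**Figure D2:**
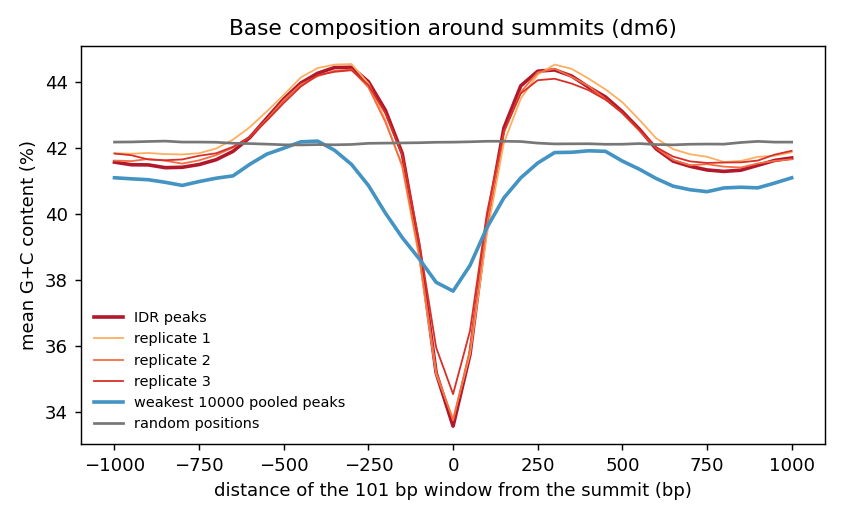
Mean G+C content (%) of windows reaching 50 bp to each side, by distance from the summit (bp) for the 8513 IDR peaks, the strongest peaks of each of the 3 replicates, the weakest 10000 peaks of the pooled relaxed list and 100000 random positions. The IDR summits reach 33.6%, the weakest peaks 37.7% and random positions stay at 42.2%.

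The summits were rich in A and T. Windows reaching 50 bp to each side of the summit held 33.6% G+C, against 43.3% in the flanks 500 bp away, and 79.4% of peaks had less G+C at the summit than in their flanks. The replicate lists gave 34.0% ± 0.446 at summits and 43.3% ± 0.153 in flanks (SD, n = 3). All 4 of the strongest peaks were exceptions, with 61.4%, 52.5%, 58.4% and 56.4% G+C. Because of this, an alternative background was added after the data had been seen: 10 random positions per peak with the same G+C content at the summit, near it and in the flanks, for 8501 peaks. Against it the direction for the E-box and the C-box turned, while unmatched random positions gave ratios of 0.696 and 0.788. The C-box was 1.52 times as frequent at summits (Fisher's exact test, adjusted p = 0.00015), and the E-box ratio of 1.19 did not pass the test (adjusted p = 0.257). In the replicate lists these ratios were 1.42 ± 0.130 and 1.06 ± 0.102 (SD, n = 3). CAGCTG (1.29), CATATG (1.2), the GAGA element (2.05), GATA (1.18), DRE (2.12) and motif 1 (5.0) were then above background with adjusted p of 0.0168 or less. The call for CA repeats ended, with a ratio of 0.967 (Fisher's exact test, adjusted p = 0.950). On simulated random positions 1 of the 15 motifs passed this test, so a single call against this background can arise without enrichment. The background was not matched on distance to a TSS: 13.9% of its positions lay near one, against 32.6% of summits. Among peaks over 1 kb from a TSS, 0.898% of summits had a C-box, against 0.939% of all matched positions. These 2 shares are not like for like, since the positions were matched to peaks of every location. Summits over 500 bp from a TSS held 32.6% G+C and those nearer to one 35.5%. How far promoter location adds to the ratios above was not tested.

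**Figure D3:**
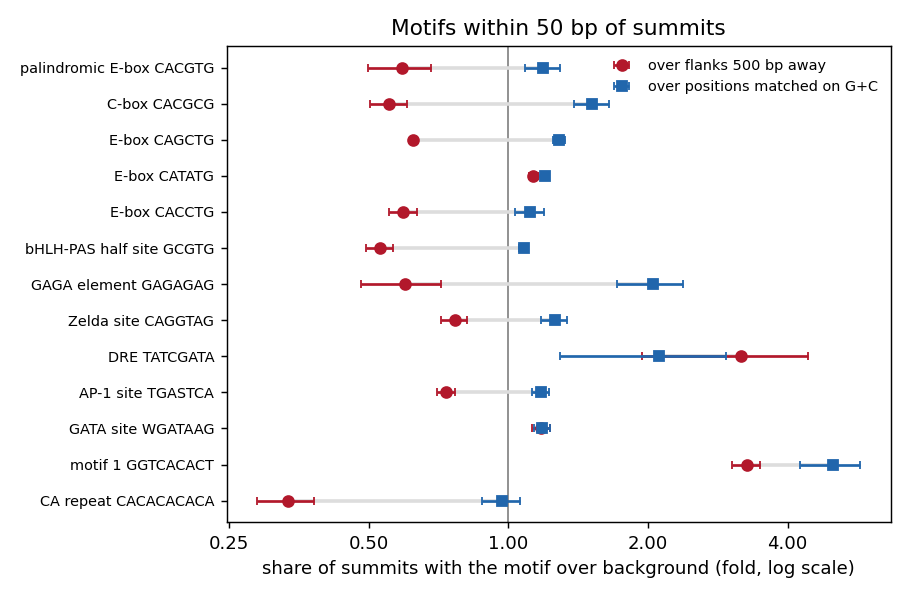
Share of summits with each motif within 50 bp, divided by the share in flanks 500 bp away (circles) or at positions matched on G+C (squares), on a log scale. Bars are 1 SD over the 3 replicate lists, drawn around the value of the IDR set and not around the replicate mean. Motifs at fewer than 30 summits are left out. The E-box moves from 0.590 to 1.19 and the C-box from 0.554 to 1.52 with the background. DRE and motif 1 lie above 1 in both, as do CATATG and GATA, which did not pass against flanks.

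Genes of the ecdysone response and of the ribosome had promoter peaks more often than matched genes. Of 13945 protein-coding genes, 3098 (22.2%) had an IDR summit within 1 kb of a TSS. Matching, here and for the lists below, was on gene length and number of TSSs and not on expression. How far promoter activity adds to the differences was not tested. In the ecdysone response list, genes regulated by or acting in signalling of the moulting hormone, 23 of 30 did (76.7%, expected 45.7% from 10000 random lists matched on gene length and number of TSSs). The permutation test gave an adjusted p of 0.0044 over 22 lists, and the replicate lists 74.4% ± 3.85 (SD, n = 3). Without replicate 2 the share was 63.3% and the adjusted p 0.066. Its members with the strongest promoter peaks were Sox14, a Sox family transcription factor (rank 48, summit at -244 bp), and E23, an ABC transporter (rank 154, with an E-box at the summit), followed by the nuclear receptor gene Eip75B (rank 191) and the lactate dehydrogenase gene Ldh (rank 207). Eip75B held 29 IDR peaks over its body and 2 kb upstream. Among cytoplasmic ribosomal protein genes, 59 of 85 had a promoter peak (69.4%, expected 22.5%, permutation test, adjusted p = 0.0022, replicate lists 76.1% ± 5.80, SD, n = 3). The strongest were at RpS19b (rank 289), RpS27 (311), RpL32 (391) and RpL34b (554); the summits assigned to RpS19b and RpL32 lay nearest to the TSS of CG5854 and CG7943.

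The list of juvenile hormone response genes did not stand apart from matched genes. In it, 6 of 15 genes had a promoter peak (40%, expected 31.7%, permutation test, adjusted p = 0.741). They were Kr-h1, br, a BTB zinc finger gene (rank 3342), Eip75B, and the juvenile hormone epoxide hydrolase genes Jheh1 (1625), Jheh2 (7934) and Jheh3 (6940). JhI-21, JhI-26, Jhe, Jhedup, Pepck1, Yp1, Yp2, Yp3 and tobi had no IDR peak near a TSS, in the body or in the 2 kb upstream. Of the receptor and its partners, 8 of 14 genes had a promoter peak (57.1%, expected 42.0%, permutation test, adjusted p = 0.632). These were nej (rank 531), Hsp83 (548), usp (2038), gce, the paralog of Met (2356), EcR (2588), tai (2914), ftz-f1 (7085) and SmydA-8 (7481). Kr-h1, br, Eip75B, usp, EcR and ftz-f1 are also members of the ecdysone response list, so these lists are not separate sets of genes. Chd64 and Nup358 had a peak only in the body or 2 kb upstream, and Met, cyc, Clk and Fkbp39 had none. The summit of the Nup358 peak was at -16 bp from the TSS of RpS27. Of 10 genes of juvenile hormone and mevalonate synthesis only Hmgs, hydroxymethylglutaryl-CoA synthase, had a promoter peak (rank 7782, with an E-box at the summit). Its signal of 109.0 was near the lowest of the IDR set (98.7), and it had no matching summit in the list of replicate 2. The gene list did not pass the permutation test (adjusted p = 0.632).

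**Figure D4:**
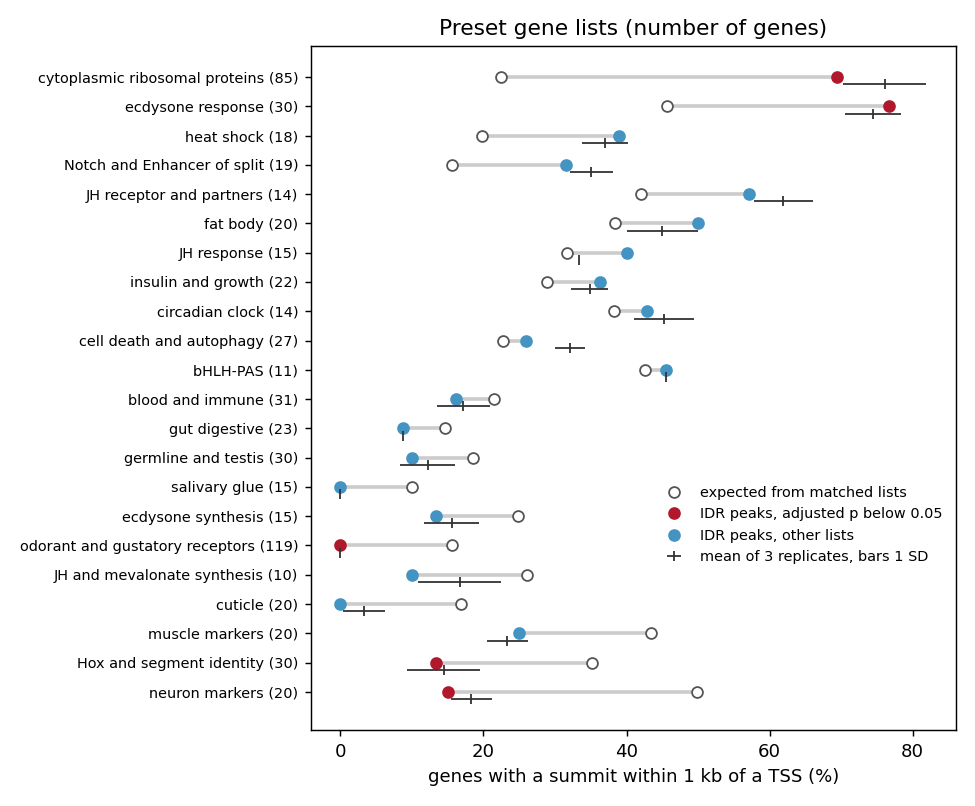
Share of genes (%) with an IDR summit within 1 kb of a TSS in each of 22 lists fixed before the data were examined; filled circles are the IDR set (red where the adjusted permutation p is below 0.05), open circles the mean of matched random lists, and ticks with bars the mean and SD of the 3 replicate lists. Ribosomal protein genes (69.4%) and ecdysone response genes (76.7%) lie above their expectation, and neuron markers (15%), Hox and segment identity genes (13.3%) and chemoreceptors (0%) below.

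Chemoreceptor, neuronal and patterning genes had fewer promoter peaks than matched genes. None of 119 odorant and gustatory receptor genes had one (expected 15.5%, permutation test, adjusted p = 0.0022). Among neuron markers 3 of 20 did (15%, expected 49.9%, permutation test, adjusted p = 0.0066): elav, an RNA-binding protein gene (rank 129), Syx1A (2023) and futsch (5741). Among Hox and segment identity genes 4 of 30 did (13.3%, expected 35.2%, permutation test, adjusted p = 0.0396): hb (4079), ptc (4202), hry (5054) and hth (6681). Leaving out any replicate ended the call for both lists, with adjusted p of 0.0572 to 0.0660 for neuron markers and 0.0660 to 0.197 for Hox and segment identity genes. The differences from expectation were then -27.6 to -27.5 points for neuron markers (-34.9 with all replicates) and -19.9 to -16.1 points for Hox and segment identity genes (-21.9). Their calls were also lost without matching, by Fisher's exact test against all genes (adjusted p = 0.688 and 0.553), and among the 4256 strongest peaks (0.131 for both). The Hox call was lost in the list of replicate 2 (0.224) and with gene bodies (0.473) too.

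The other lists did not pass the test. The shares were 50% for fat body genes (10 of 20, Lpin of rank 36, then Hnf4, FASN1 and Adh), 45.5% for bHLH-PAS genes, 42.9% for circadian clock genes (sgg of rank 119, vri, cry and Pdp1) and 38.9% for heat shock genes (Hsp27 of rank 37, Hsp26, Hsp83 and Hsp22). They were 36.4% for insulin and growth genes (InR, raptor and foxo), 31.6% for Notch and Enhancer of split genes (E(spl)m3-HLH of rank 413 and E(spl)m7-HLH of rank 451), 25.9% for cell death and autophagy genes (hid of rank 232 and Diap1 of rank 368) and 25% for muscle markers (Msp300 of rank 144). Blood and immune genes stood at 16.1%, ecdysone synthesis genes at 13.3% (shd and mld), germline and testis genes at 10% and gut digestive genes at 8.70%. No promoter peak was found at the 15 salivary glue genes or the 20 cuticle genes. The smallest adjusted p among these lists was 0.154, for cuticle genes, which passed by Fisher's exact test without matching (adjusted p = 0.0452). Of 290 tRNA genes, 20.3% had a summit within 1 kb, against 10.5% ± 2.83 (SD) in circular shifts (permutation test, 2-sided, p = 0.0040), and the replicate lists gave 22.6% ± 5.62 (SD, n = 3).

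Strong peaks lay near a TSS more often than weak ones. The share within 500 bp was 41.1% in the strongest 1703 peaks and then 32.8%, 31.0%, 29.7% and 28.4% in the next 4 equal groups by signal. The strongest and the weakest group differed by 12.7 percentage points. The trend over the 5 groups passed a permutation test with 100000 resamples (2-sided, p = 1.0e-05, the smallest these can give, adjusted p = 8.0e-05 over 16 features). The p-values that follow are also for the trend over all groups, not for the difference between the end groups. In the replicate lists the difference was 10.2 ± 2.17 points (SD, n = 3). No change of the E-box share with signal was detected: 0.763% in the strongest and 0.705% in the weakest group, a difference of 0.0583 points (permutation p = 0.863). The C-box fell by 1.12 points from the weakest to the strongest group (permutation test, adjusted p = 0.0032), and the core GCGTG fell by 4.82 points (adjusted p = 8.0e-05). The fall was not particular to these motifs. The GAGA element (-1.06 points), CAGCTG (-0.941) and CA repeats (-0.823) fell too (permutation tests, adjusted p = 0.0057, 0.0429 and 0.0017). CATATG was higher in the strongest group by 2.17 points (permutation test, adjusted p = 0.0057). The G+C content of the summits was 31.1% in the strongest and 35.6% in the weakest group.

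The dm3 and dm6 lists were close in the number and width of IDR peaks and in the overlap of replicates. The IDR set held 8515 peaks in dm3 and 8513 in dm6, with median widths of 444 and 440 bp and highest signals of 13955.4 and 13960.8. In dm3, 73.5% of the IDR peaks were overlapped in all 3 replicates. No coordinate was converted between the builds, so single peaks were not matched across them, and location, motifs and gene lists were analysed in dm6 only.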

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

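The tests of base composition and of summit position below, and the test of 1 library at Kr-h1, were chosen only after the result was seen; the tests of extra copies, of ribosomal protein genes and of mismatched hexamers were set out beforehand.

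Mitochondrial peaks stood out as signal outside the chromosome arms on which location, motifs and genes were analysed; they only took up places in the replicate lists and ranks. The dm6 relaxed list of replicate 2 held 16 mitochondrial peaks and that of replicate 3 held 7, all among their 8513 strongest, with best ranks of 13 and 31. The list of replicate 1, the pooled list and the IDR set held none. In dm3 the counts were 2, 3 and 0 for replicates 2, 3 and 1. No explanation was tested.

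The 3 strongest peaks at Kr-h1 are the pattern most worth following up. Extra copies of the region in the pulled-down DNA would raise its other peaks too. The 37 other pooled relaxed peaks within 50 kb had a median signal percentile of 50.1 within that list (quartiles 28.8 and 73.5). The highest of them reached a signal of 2462.18. The median cannot decide, because the length of the pooled list is a ceiling set by the authors. Extra copies would also lift weaker peaks of the region into the list, which could lower the median. Extra copies therefore stay open. A single library does not make the pattern, since the lowest rank of the 3 peaks over the 3 replicate lists was 3. A gap in the shared control at this place stays open, because the control's coverage was not analysed here. Binding of Met to Kr-h1 is the biological hypothesis, and with 1 group there is no untagged or hormone-free sample here to test it against.

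E-boxes and C-boxes were scarcer at summits than in flanks, with ratios of 0.590 and 0.554. Base composition is consistent with this: against positions matched on G+C the ratio was 1.19 for the E-box and 1.52 for the C-box, and against unmatched random positions 0.696 and 0.788. Summits called beside the bound site would leave more E-boxes 100 to 150 bp away than 500 to 1000 bp away. That ratio was 1.15, between the bounds of 1.1 and 1.2 set for the test, so this stays open. A difference in base composition between the pulled-down and the control library also stays open, since neither library's reads were analysed here, and no biological explanation was tested because the design has a single group.

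Most TSS-proximal peaks, 2683 of 2776 (96.6%), had neither an E-box nor a C-box within 50 bp of the summit, but so did 5644 of the 5737 other peaks (98.4%), so the lack is no trait of promoter peaks alone. Pull-down at highly transcribed promoters whatever the factor was examined through ribosomal protein genes, which are highly transcribed. They had promoter peaks in 69.4% of cases (permutation p = 0.00020, the smallest the test can give). That share counts peaks with or without a box, and binding of Met at these promoters would raise it too. The test therefore cannot decide, and this explanation stays open. Sites missed by exact matching would raise the share of hexamers 1 mismatch from CACGTG. That share at these summits was 0.650 times that of the flanks and 1.01 times that of matched positions. The ratio to flanks cannot decide, since hexamers with 4 G or C had a median ratio of 0.557 over all IDR peaks. The ratio to matched positions argues against an excess of these hexamers as a set, which could hide a single enriched variant. Base composition alone would put 13.9% of summits near a TSS, and the observed share was 2.34 times that. Binding through partner proteins, without a site of its own, was not tested and stays open.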

How the results depend on the processing

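The alternatives for strong against weak peaks and the composition-matched and random backgrounds were chosen after seeing the data; all others were fixed before the data were examined. Overlap in all 3 replicates stayed far above chance in every setting, from 53.5% with reciprocal overlap of 50% to 98.3% with whole relaxed lists, and from 79.1% to 79.5% without 1 replicate. The share near a TSS ranged from 23.2% (250 bp window, chance 7.38%) to 43.8% (1000 bp, chance 23.4%) and passed the test in every setting, also against the weakest pooled peaks (14.2%) and composition-matched positions (13.9%). The excess of strong over weak peaks near a TSS lay between 8.56 and 16.0 points in every setting. With flanks 1000 bp away the E-box ratio was 0.740 and no longer passed the exact test (adjusted p = 0.152). With the composition-matched background ratios turned above 1 for the E-box (1.19), C-box (1.52), CAGCTG (1.29), CACCTG (1.11), GCGTG (1.08), GAGA element (2.05), Zelda (1.26), AP-1 (1.17) and ecdysone response element (1.11). Unmatched random positions gave 1.41 for the GAGA element, 1.13 for AP-1 and 1.43 for the ecdysone response element, so these 3 turned without matching and the cause was not tested. The other 6 stayed below 1 there, so their ratios in the IDR set turned only with matching on G+C. Among them only the C-box and CAGCTG passed against matched positions (Fisher's exact test, adjusted p = 0.00015 and 0.00072). CACCTG had a mean matched ratio of 0.950 ± 0.0787 in the replicate lists (SD, n = 3), which stayed below 1. The ecdysone response element, found at only 1 IDR summit, also turned in the list of replicate 3 (1.33). The E-box difference between strong and weak peaks, which passed no test, turned to -0.00038, -0.118 and -0.0592 points in the lists of replicates 1, 2 and 3, to -0.418 for peaks over 1 kb from a TSS, and lay between -0.298 and 0.295 without 1 replicate.

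Lists above expectation numbered 2, between 1 and 2 without 1 replicate, and 4 by Fisher's exact test without matching, which added the receptor and its partners and fat body genes (adjusted p = 0.0255 for both). Among the stronger 4256 peaks they numbered 3, with Notch and Enhancer of split genes (31.6%, permutation test, adjusted p = 0.0451). Lists below expectation numbered 3, but 1 among the stronger 4256 peaks and 1 without any of the replicates in turn. In both cases fewer peaks remained, and that 1 list was the chemoreceptors. They numbered 4 in the list of replicate 3, with muscle markers (permutation test, adjusted p = 0.0469), and 2 in that of replicate 2, with gene bodies and by Fisher's test, where cuticle genes passed (adjusted p = 0.0452). Among lists that passed no test in either setting, the difference from expectation changed sign for juvenile hormone response (-2.10 and -1.65 points in the lists of replicates 1 and 3, and from -0.615 to 5.26 without 1 replicate), fat body (-1.22, replicate 3), circadian clock (-4.04, stronger peaks), insulin and growth (-0.0855, replicate 1), muscle markers (2.79, Fisher's test) and blood and immune genes (7.03, gene body); the cause was not tested. Over all lists and settings, 172 of 198 differences kept their direction and side of the threshold, 13 lost a call, 5 gained one and 8 changed sign. Most lists passed no test in the main setting, so most of the 172 are lists that stayed without a call. The 13 losses all fell on the few lists that had passed there. Depth is unknown, so how it limits the weaker peaks cannot be said.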

Other observations

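The genes with most IDR peaks in the body and 2 kb upstream, were examined after the data had been seen. kirre, a cell adhesion gene of the immunoglobulin superfamily, had 40 peaks over 396 kb, sbb 30 over 81.1 kb, and Eip75B 29 over 116 kb. At a higher density stood tara with 22 peaks over 36.7 kb (0.600 per kb) and Mnt, a bHLH gene of the Myc and Max network, with 19 over 31.9 kb (0.596 per kb). In all, 110 genes had at least 10 peaks, and 4006 of 13945 protein-coding genes had at least 1.

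The IDR peaks with an E-box or C-box within 50 bp of the summit numbered 186 (2.18%). After the 4 strongest peaks, the next by signal were at fok (rank 112, summit at -173 bp from the TSS), E23 (rank 154, -180 bp), a C-box peak in the 3′ UTR of CG7872 (rank 221), sdk (rank 295, -158 bp) and lncRNA:CR44619 (rank 303). RpL7 had both motifs at a summit of rank 588, 23 bp downstream of its TSS. The step in signal from the third to the fourth peak was 1.54-fold, and the strongest peak had 72.1 times the median signal of the IDR set.

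Of all 2080 hexamers counted on both strands, those with the highest ratio of summit to flank held at most 1 G or C: ATATTA led with 2.60, then ATCTTA with 2.52 and TTTAAA with 2.48. CCGGAG had the lowest ratio, 0.235. The median ratio fell from 1.96 for the 36 hexamers without G or C to 0.375 for the 36 made of G and C only. CACGTG, with 0.608 on this scale (5 added to both counts), was exceeded by 165 of the 492 hexamers with 4 G or C, and CACGCG, with 0.564, by 16 of the 192 with 5.

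G+C content alone did not give the shares of summits in coding exons, in 3′ UTRs and near a TSS. Positions matched on G+C fell in coding exons in 4.18% of cases and in 3′ UTRs in 6.12%, against 0.200% and 0.729% of the summits, and near a TSS in 13.9% against 32.6%. For introns (46.2% against 45.1%, Fisher's exact test, adjusted p = 0.0507) and 5′ UTRs (0.659% against 0.541%, adjusted p = 0.228) no difference from the matched positions was detected. A hypothesis set out before the data were examined held that the E-box share rises with peak signal. No such rise was detected over the 5 groups by signal (Spearman's rho of -0.00189, permutation test of the trend, p = 0.863). The strongest group exceeded the weakest by 0.0583 points. Explanations for such a rise were therefore not weighed.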
